A study of Acacia koa with 4 samples.

How the data were processed

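RNA was measured in seedlings of Acacia koa, a leguminous tree of Hawaii. The stems of the stressed seedlings had been bent by hand, without wounding, towards each of the cardinal directions, and the unstressed seedlings had not been bent, per the labels. Each group held 2 biological replicates, each a pool of about 20 seedlings. Seedlings were frozen and powdered before total RNA was extracted, so each value is an average over leaf, stem and any root in the pool. The time between bending and freezing is not given in the sources used here. Double-stranded cDNA was labelled with the dye Cy3 and hybridised to a 1-colour NimbleGen array, with 1 pool on each of 4 arrays, per the labels' protocols.

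The deposited values are RMA intensities on a linear scale, 1 per transcript and array, which the authors made with RMA, per the submitters' processing notes. RMA corrects the probe background, brings the probe distributions of the arrays together and summarises the probes of a transcript into 1 value. The software version and settings are not given in the sources used here. A value rested on up to 18 probes per the file headers, and 2 transcripts had fewer, with a minimum of 9. Fold differences of very dim transcripts, near the background, and of very bright ones, near the top of the scale, may be understated. RMA also assumes that most transcripts do not change, so a fall or rise common to most of them would have been removed. The deposited table of the whole series held the same intensities as the array files, with a largest difference of 0. A further column in the array files, which carries a standard error on an unexplained scale, was not used. No detection call accompanied the intensities.

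Each of the 4000 transcripts carried an identifier and the description of a similar protein. These descriptions, 1869 of them distinct, are the names used in the results. No genome or gene annotation of koa was used here, so no genome coordinates are given. Transcripts that share a description may be close relatives whose RNAs bind each other's probes, so values within a gene family are not fully separate measurements.

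Intensities were taken to log2, and stressed pools were compared with unstressed pools with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the group as the only term and 2 residual degrees of freedom. Adjusted p-values are limma's after Benjamini-Hochberg adjustment over all 4000 transcripts, with a threshold of 0.05. Transcripts past it are called here. No transcript was filtered out and nothing was added to the intensities. A fold is the ratio of the geometric mean intensities of the 2 pools in each group, and the intervals given with folds are limma's 95% confidence intervals, unadjusted for the number of transcripts. The number of arrays limits the precision. Limma's p-values rest on the spread between these pools, moderated by a prior from all transcripts that counts as 2.93 degrees of freedom. A permutation of 2 against 2 arrays cannot give a two-sided p below 0.333, so no permutation test was used. As a description that needs no variance estimate, transcripts were counted as separated by 2-fold when the dimmer of the brighter group's arrays was at least 2 times the brighter of the dimmer group's arrays.

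Before the data were examined, 23 gene lists were set as search terms applied to the descriptions, and a transcript could belong to several. The 22 lists with at least 5 members were tested with limma's camera, two-sided, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation and limma's fry, which asks whether a list's own members move one way, were run as alternatives. Fisher's exact test, two-sided and adjusted over the lists, compared the share of members called higher with the share among all other transcripts. It treats transcripts as independent, which members of a gene family are not, and does not measure the spread between pools. Search terms caught some unintended members: 9 of the 33 transcripts in the jasmonate list were rectifying ion channels, 104 of the 398 in the transcription factor list were CCHC zinc fingers, and 1 of the 46 in the ribosomal list was a ribosomal protein kinase. These were kept.

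The rule for named transcripts was also set before the data were examined. It took the 12 largest differences in each direction among called transcripts, 1 per distinct description. Where fewer than 5 were called in a direction, it took the 12 largest differences among transcripts whose stressed values both lay on the same side of both unstressed values, to be given as values. It also took up to 4 members of each list with the smallest p.

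The fit was tested on simulated arrays with the real transcripts' means and the variances that eBayes gave them, over 20 runs. In these, 200 of 4000 transcripts were changed. Noise was drawn independently for each transcript and array, without correlation between transcripts or an effect of the replicate number. The fit recovered 93.75% of 2-fold and 99.8% of 4-fold changes, with 5.78% false calls among the calls. The variances from eBayes are drawn towards a common value. The 200 changed transcripts also exceed the 38 called in the data, which eases the adjusted threshold. Recovery in the real data may therefore be lower. In separate runs, camera called a list shifted by 0.5 on the log2 scale in 100%. That shift is larger than the mean difference of any real list (at most 0.18), and correlated members were not simulated. These runs therefore do not show how well camera works on the real lists.

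The alternatives were quantile normalization applied again, centring each array on its median, cyclic loess, the table of the whole series, leaving out the dimmest 25% of transcripts, adding 50 before log2, an intensity trend with a robust prior, the replicate number as a block, leaving out each array in turn, and an adjusted p threshold of 0.10. A filter that left out 177 transcripts with a mean log2 intensity under 6 was added after seeing the data. The 4 arrays lay on 1 slide in the order of the groups, per the array identifiers, so no slide effect separates the groups, and position on the slide and group cannot be told apart.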

Results

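The series measured transcript levels in koa seedlings whose stems had been bent and in seedlings left unbent, to ask which transcripts respond to a mechanical stimulus. It held 4 arrays, 2 from unstressed and 2 from stressed pools, each with an RMA intensity for 4000 transcripts. Median intensities were 981 and 1010 in unstressed replicates 1 and 2, and 991 and 1018 in stressed replicates 1 and 2. Log2 intensities correlated across transcripts at r = 0.983 between the unstressed pools and 0.992 between the stressed pools, against 0.974 to 0.985 between pools of different groups. The correlations are over transcripts, which are not independent replicates. The unstressed pools differed more from each other (SD of the log2 difference 0.37) than the stressed pools did (SD 0.26).

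In stressed pools levels were higher for 37 transcripts and lower for 1, an iron-storage ferritin, out of 4000 tested (limma, adjusted p under 0.05). Transcription factors and zinc finger proteins were over-represented among the 37, with 15 of them in that list (Fisher's exact test, p adjusted over the lists = 1.9e-05, but 0.82 without stressed replicate 2). Fisher's test treats transcripts as independent, so its p does not measure the spread between pools. The list follows its search terms, which missed zinc-finger protein 1 (A72822) and the EREBP-3 homolog (A62860), both among the 37. The 37 were 2.07-fold to 17.96-fold higher, with a median of 4.19-fold, and 19 of the 38 called transcripts differed by at least 4-fold. At an unadjusted p under 0.05, 220 transcripts differed, 153 higher and 67 lower. The median log2 difference over all transcripts was −0.04. The count depended on single arrays. It was 25 without unstressed replicate 1, 27 without unstressed replicate 2, 10 without stressed replicate 1 and 8 without stressed replicate 2.

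**Figure D1:**
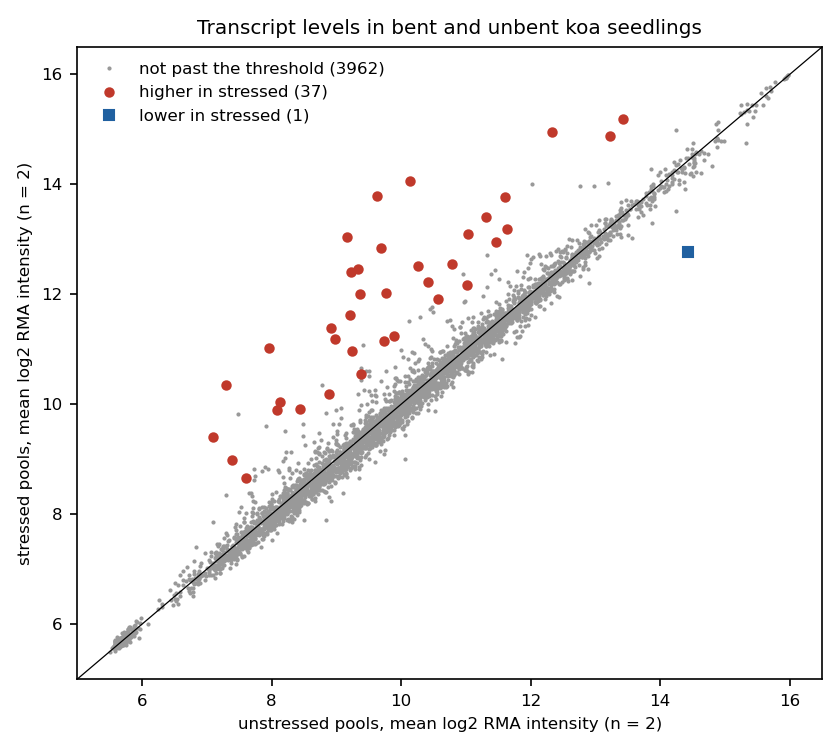
Each point is 1 of the 4000 transcripts, with the mean log2 RMA intensity of the 2 unstressed pools on the x axis and of the 2 stressed pools on the y axis, and the line marks equal levels. The 37 transcripts called higher (red) lie above the line across the range of intensities, and the 1 called lower (blue square) lies below it at high intensity.

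The largest difference was that of A142190, described as a RING finger protein, a class that often acts in tagging proteins for breakdown. Its log2 intensity was 9.63 ± 0.18 (SD, n = 2) in unstressed and 13.79 ± 0.29 (SD, n = 2) in stressed pools, 17.96-fold higher (95% confidence interval 12.8 to 25.3, limma adjusted p = 0.0035). Zinc-finger protein 1 (A72822) was 15.2-fold higher (12.1 to 19.0, adjusted p = 0.0029), and a further zinc finger protein (A75527) was 14.8-fold higher (9.87 to 22.3, adjusted p = 0.0059). A homolog of EREBP-3 (A62860), a member of the family of factors that bind the ethylene response element, was 9.08-fold higher (7.07 to 11.7). A protein phosphatase 2C (A127474), of a family that includes brakes on abscisic acid signalling, was 8.87-fold higher (6.94 to 11.3). The dehydration-responsive element-binding protein A188453, of a family that acts in drought and cold responses, was 8.79-fold higher (6.70 to 11.5). Members of the WRKY family, plant transcription factors best known from defence responses, made up 4 of the 12 largest differences. They were A406475 (8.42-fold higher), A357137 (WRKY27, 8.30-fold), A387921 (WRKY20, 6.26-fold) and A54103 (WRKY108715, 5.54-fold). The other two were the RING-type zinc finger A31187 (6.16-fold) and the LysM receptor kinase A20036 (5.38-fold), of a class that perceives chitin and related sugars at the cell surface. The 9 transcripts of this paragraph after the top 3 had limma adjusted p-values from 0.0035 to 0.0238. The largest 8 of the 12 were also called in each fit that left out 1 array, while A387921 was called in none of these 4 fits. A31187 and A54103 were not called without stressed replicate 2, and A20036 was called neither without stressed replicate 1 nor without stressed replicate 2.

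Ferritin-3 (A8737), a plastid iron-storage protein, was the only transcript called lower. Its log2 intensity fell by 1.65, from 14.43 ± 0.10 (SD, n = 2) to 12.77 ± 0.16 (SD, n = 2), a level 3.14-fold lower in stressed pools (2.44 to 4.04, limma adjusted p = 0.0171). Without unstressed replicate 1, stressed replicate 1 or stressed replicate 2 it was not called (adjusted p = 0.0550, 0.1046 and 0.1783), at differences of −1.54 to −1.76 over all fits that left out 1 array. The other 11 of the largest negative differences among separated transcripts did not pass the threshold. The largest of these were a nodulin (A268015, log2 difference −1.05, adjusted p = 0.17), a cellulose synthase (A103931, −0.74, adjusted p = 0.25), an acidic chitinase (A2721, −0.73, adjusted p = 0.60) and an oligopeptide transporter (A35501, −0.70, adjusted p = 0.19). The remaining 7 had log2 differences from −0.68 to −0.59 and adjusted p-values from 0.28 to 0.99. They were an adenosylhomocysteinase (A139246), a pectinesterase (A244101), auxin-induced 5NG4 proteins (A247811 and A17038), a CC-NBS-LRR protein (A368623), a peroxidase (A30691) and a caspase-like peptidase (A77706).

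**Figure D2:**
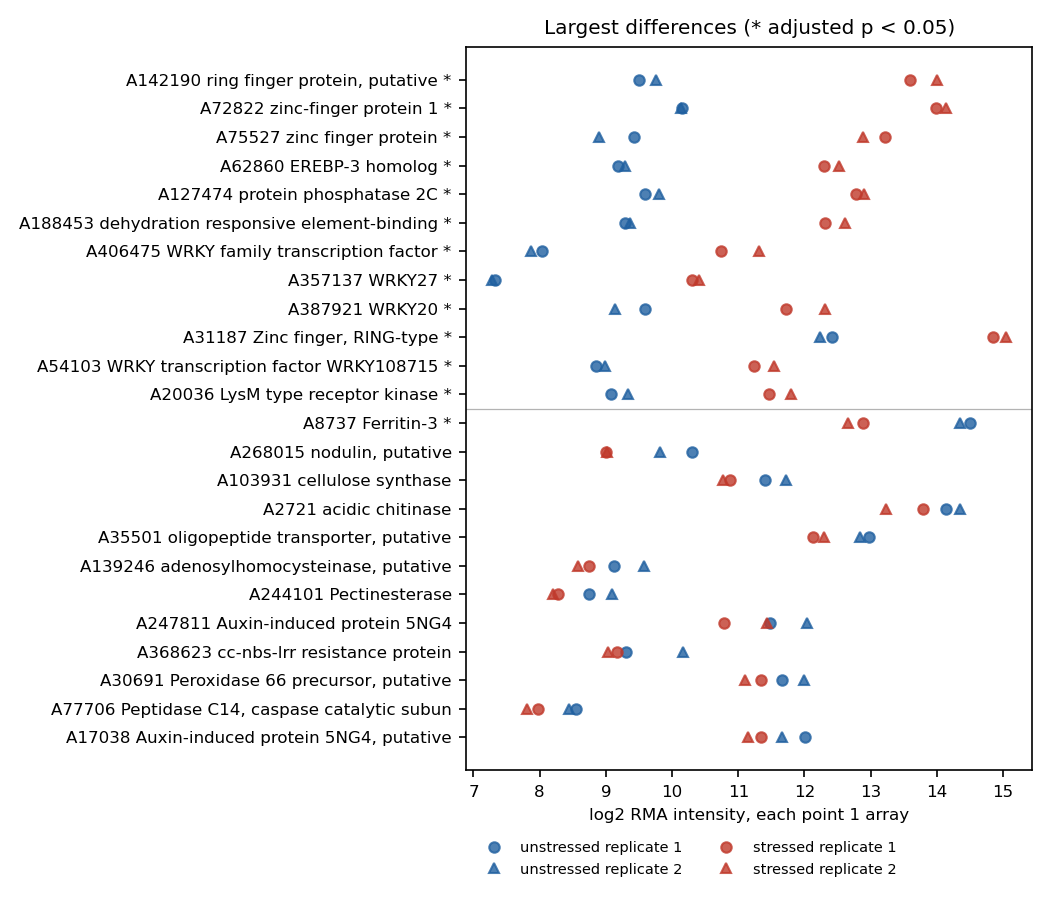
Each row is a transcript, with the log2 RMA intensity of each of the 4 arrays on the x axis. The upper 12 rows are the largest differences among transcripts called higher and the lower 12 the most negative differences among separated transcripts, where only ferritin-3 was called; in every row both stressed arrays lie on the same side of both unstressed arrays.

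In the ethylene list, 3 of 37 transcripts rose (4 when adjusted over the list alone) and none fell. They were an ethylene-responsive element-binding protein (A21136, 4.50-fold higher, 3.62 to 5.59, limma adjusted p = 0.0056), 1-aminocyclopropane-1-carboxylate synthase (A122958, 3.73-fold higher, 3.01 to 4.62, adjusted p = 0.0063) and an ethylene-responsive transcription factor (A12798, 3.41-fold higher, 2.73 to 4.27, adjusted p = 0.0087). The synthase makes the direct precursor of ethylene and often limits its production. A further ethylene-responsive factor (A27414) was 1.57-fold higher at an adjusted p of 0.23. The EREBP-3 homolog A62860, 9.08-fold higher, was missed by the search terms, so the counts and tests of this list leave it out. The list as a whole had a mean log2 difference of 0.18 against a median of 0.02, with 19 members positive and 18 negative. Camera put it above the other transcripts (adjusted p = 0.027), but not with an estimated correlation (adjusted p = 0.94 with an estimated correlation). Its camera adjusted p was 0.098 without unstressed replicate 1, 0.092 without unstressed replicate 2 and 0.10 without stressed replicate 2. Its share of members called higher, 8.11% against 0.858% of other transcripts, did not pass Fisher's exact test adjusted over the lists (p = 0.0502). That adjusted p was 0.023 without unstressed replicate 1, 0.018 without unstressed replicate 2 and 1 without either of the stressed replicates. The 3 called members were called without either unstressed replicate, but not without stressed replicate 1 or stressed replicate 2.

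In the touch and calcium signalling list, 2 of 73 transcripts rose (4 when adjusted over the list alone) and none fell. An EF-hand protein (A17246) was 2.95-fold higher (2.34 to 3.72, limma adjusted p = 0.016) and a calcium-binding protein similar to an olive allergen (A16350) was 2.56-fold higher (2.08 to 3.14, adjusted p = 0.017). A calmodulin-binding protein (A18865, 2.62-fold higher) and a calmodulin (A1097, 2.22-fold higher) passed only when adjusted over the list alone, each with an adjusted p of 0.069 over all transcripts. Calmodulins and EF-hand proteins bind calcium and relay its signals. The list's mean log2 difference was 0.10 and its median 0.00, with camera adjusted p = 0.027 and adjusted p = 0.94 with an estimated correlation. Camera's adjusted p was 0.30 without unstressed replicate 1, 0.16 without stressed replicate 2 and 0.10 without the dimmest 25% of transcripts. The share called higher was 2.74%, against 0.891% of other transcripts (Fisher's exact test, adjusted p = 0.80). Neither A17246 nor A16350 was called in any of the 4 fits that left out 1 array.

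The list of WRKY, MYB, NAC and related transcription factors and of zinc finger proteins held 398 transcripts. Of these, 15 rose (24 when adjusted over the list alone) and none fell. This was 3.77% of members, against 22 of 3602 other transcripts (0.611%), a difference in Fisher's exact test (p = 8.6e-07, adjusted over the lists p = 1.9e-05). That test takes the members as independent, although relatives may bind each other's probes. The 4 members with the smallest p were A357137, A31187, A75527 and A54103, given above. The 15 need not all be transcription factors, as A31187 and A47392 are described as RING zinc fingers and A433991 as a CCHC zinc finger. Conversely, the 22 others included A72822, A62860 and A188453, whose descriptions the search terms missed. The rest of the list did not share this direction, as 280 members were negative and 118 positive. The median log2 difference was −0.10, the mean was 0.02 and camera pointed down without passing the threshold (adjusted p = 0.80). The number of members called higher was 8 without unstressed replicate 1, 9 without unstressed replicate 2, 5 without stressed replicate 1 and 3 without stressed replicate 2. Fisher's adjusted p was 0.023, 0.013, 0.035 and 0.82 in these fits, in that order. Without unstressed replicate 2 the mean was −0.07 and camera called the list lower (adjusted p = 0.029).

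In the abscisic acid and drought list, 2 of 43 transcripts rose, over all transcripts and adjusted over the list alone. Besides A188453, abscisic acid 8'-hydroxylase (A48201), which opens the breakdown of this drought hormone, was 4.62-fold higher (3.66 to 5.83, limma adjusted p = 0.0059). Other dehydration-responsive element-binding proteins differed by 1.40 (A497171, adjusted p = 0.33) and −0.32 (A36922, adjusted p = 0.98) on the log2 scale. In the salicylate and pathogenesis list, 2 of 179 transcripts rose, with the same number when adjusted over the list alone. Both were NBS-LRR proteins, a class of intracellular immune receptors (A519411, 4.92-fold higher, adjusted p = 0.020, and A209791, 3.47-fold higher, adjusted p = 0.027). A further such protein (A620627) was 5.09-fold higher at an adjusted p of 0.087, and the resistance protein A602467 was 1.85-fold higher at 0.15. In the receptor and MAP kinase list, 2 of 187 rose, again with the same number when adjusted over the list alone. They were A20036 and mitogen-activated protein kinase 2 (A23526, 4.19-fold higher, 2.92 to 6.02, adjusted p = 0.024). The upstream kinase A101795 was 1.59-fold higher (adjusted p = 0.17) and the wall-associated kinase A147420 1.64-fold higher (adjusted p = 0.24). Camera called none of these 3 lists (adjusted p = 0.80, 0.89 and 0.96). The shares called higher were 4.65%, 1.12% and 1.07%, against 0.885%, 0.916% and 0.918% of other transcripts (Fisher's exact test, adjusted p = 0.43, 1 and 1). A209791 and A23526 were called in none of the 4 fits that left out 1 array. A519411 was called only without unstressed replicate 1, and A48201 only without unstressed replicate 1 or unstressed replicate 2.

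No transcript of the 5 lists on cell walls and phenolic compounds was called by limma, over all transcripts or adjusted over the list alone. Fisher's adjusted p was 1 for these and all other tested lists with no transcript called higher. At an unadjusted p under 0.05 there were 3 in the xyloglucan, 1 in the wall structural, 1 in the cellulose, 1 in the lignin and 3 in the flavonoid list. The cellulose and secondary wall list (45 transcripts) nevertheless lay below the other transcripts, with a mean log2 difference of −0.15, 35 members negative and 10 positive (camera adjusted p = 0.027, adjusted p = 0.94 with an estimated correlation). Of its 24 cellulose synthases, which make the main load-bearing polymer of the wall, 16 were negative, a smaller share than in the whole list. Besides A103931, the synthases named by the rule were at −0.49 (A28019) and −0.39 (A38477). An endoxylanase (A335569) was at −0.36. The shift was the same in sign in each fit that left out 1 array (−0.157 to −0.139), but camera's adjusted p was 0.098 without unstressed replicate 1, 0.092 without unstressed replicate 2 and 0.14 without stressed replicate 1. It was 0.086 without the dimmest 25% of transcripts. The xyloglucan and wall-loosening list (83 transcripts, camera adjusted p = 0.89) held pectinesterases with opposite signs, A244101 at −0.68 and A33509 at 0.78, besides a pectin methylesterase at 0.35 (A4621) and a xyloglucan enzyme at 0.40 (A115150). Among 8 wall structural proteins (adjusted p = 0.99), fasciclin-like arabinogalactan protein A60373 was at 0.42, fasciclin-like A81703 at −0.25 and glycine-rich A1850 at −0.26. In the lignin list (45 transcripts, adjusted p = 0.76) the laccases A213127 and A155477 were at −0.38 and −0.29, 4-coumarate-CoA ligase (A188183) at −0.27 and cinnamate 4-hydroxylase (A1497) at 0.74. In the flavonoid list (34 transcripts, adjusted p = 0.79) the flavonoid 3'-hydroxylases A66450 and A53995 were at 0.87 and 0.91, a chalcone and stilbene synthase (A50284) at −0.39 and a chalcone isomerase (A106752) at −0.32.

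The lists for jasmonate, gibberellin, auxin, oxidative stress and heat shock also held no transcript called by limma, over all transcripts or adjusted over the list alone. At an unadjusted p under 0.05 there were 0, 3, 3, 13 and 2, in that order. Of 33 jasmonate members (camera adjusted p = 0.89), 21 were lipoxygenases and 9 were ion channels caught by the search terms. Other steps of jasmonate synthesis and signalling were thus hardly covered. Lipoxygenases, a class that includes the enzymes that begin jasmonate synthesis, were at 0.37 (A102163) and 0.50 (A1769). The ion channels were at −0.36 (A44358) and −0.29 (A68698). Among 38 gibberellin members (adjusted p = 0.89), a gibberellin 20-oxidase (A37154) was at 0.56 and the DELLA growth repressor GAI (A5755) at 0.50, with ent-kaurene oxidase (A68695) at −0.30 and a gibberellin 3-beta-hydroxylase (A185209) at −0.24. Among 56 auxin members (adjusted p = 0.55), the auxin-induced transcripts A69580 and A43833 were 2.41-fold and 2.15-fold higher, at limma adjusted p of 0.24 and 0.32, while A17038 was at −0.59 and an auxin symporter (A57581) at −0.30. Of the 126 members for oxidative stress (camera adjusted p = 0.29, but 0.038 without stressed replicate 2), a lignin biosynthetic peroxidase (A763) was 1.99-fold higher (limma adjusted p = 0.099) and a lactoylglutathione lyase (A10453) 1.94-fold higher (0.35). A respiratory burst oxidase (A13589) was at 0.57 and a glutathione-related transcript (A32832) at −0.47. Of the 86 members for heat shock (camera adjusted p = 0.90), a heat shock protein binding protein (A92514) was 1.79-fold higher (limma adjusted p = 0.091). The heat shock factors A53703, A23211 and A5724 were at 0.50, 0.46 and −0.29.

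The cellulose and secondary wall list, which camera called lower as given above, also served as a marker of xylem. Among the other lists that served as markers of organs and of general RNA state, camera called the ribosomal proteins only. The 46 cytosolic ribosomal transcripts had a mean log2 difference of 0.12, with 37 positive and 9 negative (camera adjusted p = 0.0038, adjusted p = 0.94 with an estimated correlation). None of the 46 was called by limma (2 had an unadjusted p under 0.05), and without unstressed replicate 1 the mean was −0.01 (camera adjusted p = 0.96). Their mean log2 intensity was 10.99 in that array and 11.26, 11.22 and 11.27 in unstressed replicate 2, stressed replicate 1 and stressed replicate 2. The values of L14 (A3416), a 40S protein (A2643) and a 60S protein (A1562) were 0.78, 0.33 and 0.23, and that of a ribosomal protein S6 kinase (A132084) was −0.35. The 5 transcripts of the photosynthesis list, meant as markers of leaf, had a mean log2 difference of −0.09 (camera adjusted p = 0.80). A ferredoxin-dependent sulfite reductase (A8136), caught by the term ferredoxin and no leaf marker, was at −0.17. Of the 15 root and nodule transcripts (adjusted p = 0.90), the nodulin A268015 passed when adjusted over the list alone. The nitrate transporters A8361 and A21298 were at −0.21 and 0.18, and a chloroplast pentose phosphate transporter (A26202), which is no root marker, at −0.26. Among 117 cytoskeleton and household transcripts (adjusted p = 0.57) the ubiquitin ligase A18201 was 2.09-fold higher (limma adjusted p = 0.17). The ubiquitin ligases A140259 and A213327 were at −0.38 and −0.40, and an actin-binding protein (A220261) at 0.39. Among 23 cell cycle transcripts (camera adjusted p = 0.86, but 0.036 without unstressed replicate 2) a cyclin-dependent kinase (A9589) was at 0.31, cyclin D3 (A75494) at −0.27, and a kinase inhibitor (A63946) and a histone methyltransferase (A136276) both at −0.17. Among 15 aquaporins (adjusted p = 0.80), channels for water, the values of A290063, A12359, A2563 and A14389 were −0.50, −0.33, −0.20 and 0.19. The cysteine and mimosine list held 1 transcript, which was not called. No transcript of the photosynthesis, root, household, cell cycle and aquaporin lists was called by limma over all transcripts, and 0, 1, 4, 0 and 0 of them had an unadjusted p under 0.05.

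**Figure D3:**
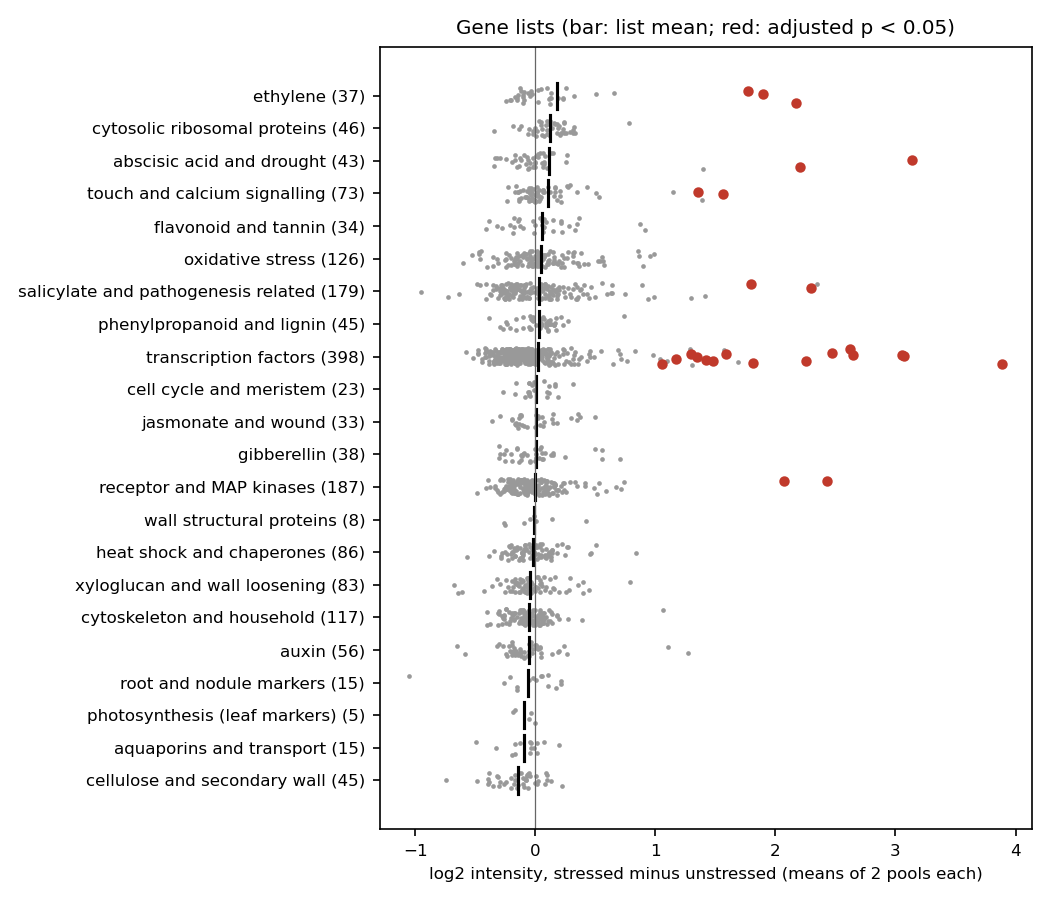
Each point is a transcript, placed by its log2 difference between stressed and unstressed pools (x axis, means of 2 pools each) in the row of its gene list, with the number of members in brackets; black bars mark list means and red points transcripts called over all 4000. Red points appear in the ethylene, abscisic acid, touch, salicylate, transcription factor and kinase rows, all to the right of 0.

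A count without a variance estimate gave a similar number, with 43 transcripts separated by at least 2-fold, 42 of them higher and 1 lower in stressed pools. All 38 called transcripts had stressed values on the same side of both unstressed values, as had 1259 transcripts (31.5%) in total, where chance gives 33.3%. The 4 arrays can be split 2 against 2 in other ways. The split of replicate 1 against replicate 2 arrays gave 11 transcripts separated by 2-fold, all higher in the replicate 1 arrays, and 0 called by limma, with 477 at an unadjusted p under 0.05. The last split gave 0 separated by 2-fold and 0 called by limma, with 21 at an unadjusted p under 0.05.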

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

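The filter on transcripts with a mean log2 intensity under 6 was chosen after seeing the data, and all other alternatives were planned. The count of 38 called transcripts was 34 after quantile normalization, 36 after median centring, 37 after cyclic loess, 38 from the series table, 40 without the dimmest 25%, 33 with 50 added, 44 without the floor transcripts, 45 with a trend and robust prior and 49 at an adjusted p threshold of 0.10. Over these scalings the median difference of all transcripts stayed between −0.05 and −0.01. Leaving out 1 array gave 8 to 27 called transcripts, 8 to 26 higher and 0 to 1 lower. Each such fit has 1 residual degree of freedom and assumes that the lone array varies like the other group's pools, so fewer calls follow from its construction too. Of the 38 called transcripts, 24 were called without unstressed replicate 1, 24 without unstressed replicate 2, 10 without stressed replicate 1 and 8 without stressed replicate 2. Over all alternatives, which refit the same arrays, these 38 kept their direction in 491 of 491 tests and stayed past the threshold in 393. The direction was largely fixed beforehand, so its count is no separate evidence. All 38 had stressed values on the same side of both unstressed values, so leaving out 1 array could not reverse them. The replicate block, the trend and the filters left the differences unchanged, and the series table held the same intensities. The 43 transcripts separated by 2-fold stayed within 1.5 times that number in each alternative run for them. Leaving out an array can only keep or raise this count, so those fits could not have shown a loss.

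Both groups have replicates 1 and 2, but nothing in the labels says that a number marks a shared batch, and only 2 pairs exist. The deviations of same-numbered arrays from their group means correlated at 0.505 across transcripts. With the number as a replicate block, 139 transcripts were called, 123 higher and 16 lower, among them all 38. Statements elsewhere that a transcript or the members of a list were not called hold for the fits without the block. The same goes for ferritin-3 as the only transcript called lower.

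The number of lists called by camera was 4. It was 2 without the dimmest 25%, 0 with an estimated correlation, 0 with fry, and 0 to 4 when 1 array was left out. Of the 4 called lists the ribosomal list changed sign, without unstressed replicate 1. Lists that were not called changed sign too, and the cause was not tested. The mean of the transcription factor list turned from 0.018 to −0.072 without unstressed replicate 2, while camera had pointed down in the main fit already. The kinase list had a mean of 0.0012 after quantile normalization, 0.038 after cyclic loess and 0.014 without the dimmest 25%. After median centring the jasmonate, gibberellin and cell cycle lists were at −0.00907, −0.00942 and −0.00355, and without the dimmest 25% the gibberellin list was at −0.014. After cyclic loess the wall structural and heat shock lists were at 0.031 and 0.012. When 1 array was left out, list means ranged from −0.063 to 0.17 (flavonoid), −0.023 to 0.012 (kinase), −0.013 to 0.26 (ribosomal), −0.12 to 0.14 (cell cycle), −0.21 to 0.022 (aquaporins), −0.031 to 0.0055 (wall structural), −0.062 to 0.068 (jasmonate), −0.013 to 0.019 (gibberellin), −0.022 to 0.079 (salicylate) and −0.072 to 0.11 (transcription factors).

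No background measure was used, so how far background limits each transcript is unknown. Without the dimmest 25% of transcripts camera no longer called the touch (adjusted p = 0.102) and cellulose (0.086) lists, and the cause was not tested. In all, 177 had a mean log2 intensity under 6 (median 5.70), none of which was called by limma and 0 of which had an unadjusted p under 0.05, while the lowest unstressed log2 value of a called transcript was 6.93.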

Other observations

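The transcripts and families named in this part, and the tests of the clock list, the intensity trend, the floor and a common fall, were chosen after the results were seen, while the fits that left out 1 array were planned. Counted by family, 7 of 30 WRKY transcription factors were called higher, as were 5 of 45 ERF, DREB and AP2 factors, 3 of 36 RING finger proteins, 2 of 27 protein phosphatases 2C and 2 of 34 NAC factors. These families were picked from the calls, so no test of their counts is given. Limma called 0 of 79 transcripts whose description names MYB, with 7 at an unadjusted p under 0.05, and of 105 CCHC zinc fingers 1 was called. Besides the WRKY members named in the results, A10271 (WRKY27), A12297 (WRKY23) and A23796 (WRKY39) were 2.68-fold, 2.54-fold and 2.26-fold higher (limma adjusted p = 0.020, 0.030 and 0.039). Members of a family may bind each other's probes, so these counts are not of fully independent transcripts. Without unstressed replicate 1, unstressed replicate 2, stressed replicate 1 and stressed replicate 2, in that order, 4, 5, 3 and 2 WRKY factors were called higher. In the same order the numbers were 4, 4, 2 and 2 ERF, DREB and AP2 factors, 2, 2, 2 and 1 RING finger proteins, 2, 2, 1 and 1 protein phosphatases 2C and 1, 1, 0 and 0 NAC factors. A23796 was called in none of the 4 fits that left out 1 array, A10271 only without unstressed replicate 1 and A12297 only without unstressed replicate 2.

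Of the 38 called transcripts 26 belonged to at least 1 list, and others lay outside every list. Of 5 transcripts described as MAP kinases, which pass signals from the cell surface, 2 were called, A23526 from the kinase list and A15040 (4.26-fold higher, limma adjusted p = 0.0087). Of 11 epimerases, 2 were called, and both act on glucuronate-type sugar nucleotides that feed cell wall polysaccharides. They were UDP-D-glucuronic acid 4-epimerase (A8782, 3.38-fold higher, limma adjusted p = 0.037) and UDP-glucuronate 5-epimerase (A3401, 3.15-fold higher, adjusted p = 0.022). A second protein phosphatase 2C (A42479) was 4.79-fold higher and a syntaxin (A409657), a protein of vesicle fusion, 3.33-fold higher (adjusted p = 0.0061 and 0.017). None of A15040, A8782, A3401, A42479 and A409657 was called without stressed replicate 1 or stressed replicate 2, and A8782 was not called without unstressed replicate 1 either. The second ferritin on the array, ferritin-1 (A201730), was at a log2 difference of −0.33 and was not called (adjusted p = 0.87). Of the 177 transcripts at the floor of the array, 152 matched protein records of the type RefSeq gives mainly to bacterial, viral and organelle genomes (YP_), out of 168 such records on the array.

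The replicate 1 arrays differed from the replicate 2 arrays alike in both groups, and of 11 transcripts separated by 2-fold between them, polygalacturonases A31734 and A30233 (5.38-fold and 5.31-fold higher in replicate 1) and MYB131 (A6518, 4.93-fold) differed most. The MYB factors A65431 and A52301, a carboxylesterase (A13533) and the gibberellin receptor GID1 (A23928) were 2.29-fold to 3.26-fold higher. The other 4 were an early light-induced protein (A288, 2.62-fold) and all 3 transcripts described as LATE ELONGATED HYPOCOTYL, a morning clock factor (A353, A3704 and A8698, 2.62-fold to 3.37-fold). A smooth curve of intensity explained 1.90% of the variance of the replicate difference in unstressed and 0.367% in stressed pools. Little of the difference in the deposited values thus followed intensity. RMA had already brought the probe distributions of the arrays together, so the test cannot decide on an array difference before that step. Harvest at another time of day or light state may explain the pattern, but stays open, since a list of 24 clock and light transcripts, which holds these last 4, differed between replicate numbers at the 83.1 percentile of 10000 expression-matched random lists, and the 20 without them at the 63.6 percentile.

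In the fit without the replicate block, calls were 37 higher against 1 lower. A lack of room to fall near the floor would spare bright transcripts. Of the 15 called transcripts above the median unstressed level, 14 were higher (93.3%, exact binomial 95% interval 68.1 to 99.8). The interval treats transcripts as independent, although they share the same arrays and were chosen by passing the threshold. It does not measure the spread between pools. The count itself argues against a lack of room to fall, for these 15 only. A fall common to most transcripts, removed by the authors' normalization, could also hide lower calls. Adding a common fall to the stressed arrays decided nothing: calls went from 18 higher and 1 lower at 0.40 on the log2 scale to 60 and 2172 at 0.45, where most transcripts pass the threshold together. Such a fall and a response in which more transcripts rise than fall both stay open.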
